A study of Mus musculus with 90 samples.

How the data were processed

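RNA from the cortex and the striatum of the right hemisphere of 45 mice was sequenced, 1 library per tissue and mouse, giving 90 libraries. The mice were C57BL6/J, 9 months old, and either wild type (WT) or homozygous for Q175, a knock-in of an expanded CAG repeat in Htt that is used as a model of Huntington's disease. Per the labels, PF-02545920, an inhibitor of the phosphodiesterase PDE10A, or its vehicle had been given by mouth once daily from the age of 5 weeks. Each tissue had 9 WT vehicle mice (5 females), 7 Q175 vehicle mice (5 females), and Q175 mice at 0.32 mg/kg (10, 5 females), 1.0 mg/kg (10, 5 females) and 3.2 mg/kg (9, 5 females). Mice are named here by arm, sex and number, so that F4 is female 4 of its arm. Replicates are separate mice, and the animal numbers in the labels tie the cortex and the striatum of each mouse.

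The authors deposited an estimated count (also called an expected count) per gene and library, which need not be a whole number, and an FPKM value, scaled by gene length and library depth. Per the submitters' processing notes CASAVA 1.8.2 was used, with no role stated. The aligner, the quantification tool, the genome build, the annotation and any use of strand are not given in the sources used here. Both tables held 38561 Ensembl mouse gene IDs without symbols. Symbols, GC content, gene length and coordinates came from GENCODE M21 on GRCm38, which may differ from the authors' build. It named 36639 of the IDs, which held 99.68% of the counts. Of the deposited counts 81.5% were whole within 1e-06, and all were rounded to whole numbers before testing. How reads shared by near-identical genes were assigned is not given, and they may have been divided between the genes. Values of hemoglobin genes, beta protocadherins, ribosomal protein genes with pseudogenes, and overlapping or antisense genes are therefore uncertain.

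Total counts ran from 30.5 M to 44.9 M in the striatum and from 37.2 M to 45.8 M in the cortex. Intervals of ratios of counts and floors of 3 counts over a group, at the 95% level, cover counting error only. The sex given in the labels matched the sex-linked transcripts in 90 of 90 libraries, and no 2 libraries, within or across groups, agreed within sampling noise (lowest chi-square per degree of freedom 3.61). The striatum and the cortex of a mouse deviated together from their groups (median r 0.13, lowest 0.017 over 45 mice), which with the animal numbers is the basis for pairing the tissues.

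The main test was edgeR's (4.0.16) quasi-likelihood F test in R 4.3.3, with TMM factors, the expression filter of edgeR, terms for the 5 arms and sex, and all 45 libraries of a tissue in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p-values of single genes come from this test throughout, and fold changes are given as log2 with their standard error (SE). The dose trend used the 36 Q175 mice with the arms coded in equal steps. Differences between the tissues used the mouse as a block. Contrasts of 2 doses and of a dose effect between tissues were added after the data were examined. The 26 gene lists, the rule for naming genes, the tests of the genotype and of each dose, and most alternatives were fixed before the data were examined.

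The lists were MSN identity (genes of medium spiny neurons, the main neurons of the striatum), indirect-pathway MSN, direct-pathway MSN, activity and CREB-target genes, cyclic nucleotide machinery, neurotransmitter receptors, clustered protocadherins beta, developmental transcription factors, p53 targets, cholesterol biosynthesis, heat shock and chaperones, oxidative phosphorylation, interferon response, astrocyte, microglia, oligodendrocyte, oligodendrocyte precursor, endothelial and pericyte, choroid plexus, ependymal, cortical excitatory neuron, cholinergic neuron, GABA interneuron, thalamus and hypothalamus, blood, and cytosolic ribosomal proteins. Each list was tested with camera of limma (3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 26 lists of a comparison. Members called were counted with adjustment over all genes tested and adjusted over the list alone. Named genes were Htt and Pde10a, the 8 higher and 8 lower called genes of mean log2 CPM of at least 0 with the largest fold change, up to 4 members per described list with the smallest p, and the 5 genes of smallest p where under 20 were called. Predicted genes without a name were passed over. Some members that this rule names are not reported here.

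A genotype score per mouse projected log2 CPM, with sex removed, on the difference between WT and all Q175 mice over the genes called between them by limma, and was scaled to 0 for the WT mean and 1 for the pooled Q175 mean. Dosed and vehicle mice were compared by a two-sided exact permutation test, adjusted over the 6 tests. For an axis built from part of the vehicle mice the test drew 2000 permutations. A score of the activity and CREB-target genes, the mean log2 CPM of its 24 members minus the Q175 vehicle mean, was tested in the same way over 9 tests and was added after the data were examined.

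Alternatives were DESeq2 (1.42.0) and its size factors, limma voom with quality weights, limma on log2(FPKM + 0.1) and log2(FPKM + 1), no filter or a stricter one (CPM of at least 1 in 7 libraries), no sex term, females only, sequencing lane as a term, the sex and replicate number as a block, and only the libraries of the groups compared. In addition, each library was left out in turn, dose was coded in mg/kg, and the score was built on other genes, weights or mice. Offsets per library for GC content and gene length (splines with 5 degrees of freedom) and the omission of the 1.0 mg/kg cortex libraries F1 and F4 were added after the data were examined. The offsets were fitted without regard to arm, so they also take out any part of an arm's effect that follows GC content or length. On simulated counts with 200 changed genes, the main test recovered 97% of 2-fold and 62.7% of 1.25-fold changes for the genotype in the striatum (17258 genes). It recovered 89.4% and 59.7% for 3.2 mg/kg in the striatum (17239 genes) and 95.5% and 74.6% for 3.2 mg/kg in the cortex (17516 genes). For 0.32 mg/kg in the cortex 5.11% of its calls on simulated counts were false. With a simulated GC trend 3849 of 4020 calls were false (95.7%), and with GC and length offsets none of 167. Figures were drawn with matplotlib 3.10.9.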

Results

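Gene expression was measured by RNA-seq in the striatum and the cortex of 45 mice, to ask how the Q175 allele changes both tissues and what the PDE10A inhibitor PF-02545920, given once daily up to the age of 9 months, does on that background. PDE10A degrades cyclic AMP and cyclic GMP and is concentrated in medium spiny neurons. Each tissue had 9 WT vehicle, 7 Q175 vehicle, 10 Q175 mice at 0.32 mg/kg, 10 at 1.0 mg/kg and 9 at 3.2 mg/kg. Errors of group values are SD over mice, and errors of log2 fold changes are SE.

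The tissue labels were first compared with marker genes in the 9 WT mice. Medium spiny neuron genes were higher in striatum than in cortex for 22 of 22 members of the MSN identity list (22 adjusted over the list alone). Pde10a was higher by 3.74 ± 0.0658 on the log2 scale (adjusted p = 5.66e-15), and Drd2, a dopamine receptor of indirect-pathway neurons, by 4.79 ± 0.0641 (adjusted p = 2.48e-16). All 10 cortical excitatory neuron genes were lower in the striatum (10 adjusted over the list alone), among them the vesicular zinc transporter Slc30a3 (-5.05 ± 0.299, adjusted p = 1.61e-09). All 13 oligodendrocyte genes and all 5 cholinergic genes were higher in the striatum. With an estimated correlation the adjusted p of these lists was 0.238 for MSN identity, 0.447 for the excitatory list, and 0.348 for the oligodendrocyte and cholinergic lists. In total 12099 of 16769 genes differed.

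Htt, the gene carrying the knock-in (chromosome 5, 34761740 to 34912534, plus strand, GRCm38), separated the genotypes in both tissues. In the striatum its level was 197.5 ± 14.5 CPM in WT mice (n = 9) and 113.8 ± 6.31 CPM in Q175 vehicle mice (n = 7), a log2 change of -0.78 ± 0.0445 (adjusted p = 4.15e-19). In the cortex it was 226.9 ± 8.53 CPM in WT and 128.4 ± 4.86 CPM in Q175 vehicle mice (-0.81 ± 0.0791, adjusted p = 3.18e-11). The lowest WT library stood at 172.7 CPM in the striatum and the highest of the 36 Q175 libraries at 140.8 CPM. No change of Htt with dose was called, with log2 changes against Q175 vehicle of 0.01 ± 0.0431, 0.07 ± 0.0433 and 0.02 ± 0.044 in the striatum and adjusted p of at least 0.374. In the cortex the changes were -0.10 ± 0.0767, -0.12 ± 0.077 and 0.01 ± 0.0783, with adjusted p of at least 0.273. The value for Htt at 1.0 mg/kg rests on cortex libraries F1 (72.74 CPM) and F4 (79.16 CPM), the other 8 lying between 123.1 and 146.3 CPM. It was -0.05 without F1, -0.07 without F4, 0.02 without both, and 0.03 with GC and length offsets. Pde10a (chromosome 17, 8525372 to 8986648, plus strand) fell from 2013 ± 333 CPM in WT striatum to 717.1 ± 45.6 CPM in Q175 vehicle striatum (-1.49 ± 0.0967, adjusted p = 3.37e-17), and in the cortex from 150.4 ± 28 to 90.56 ± 12.5 CPM (-0.72 ± 0.104, adjusted p = 4.49e-07). Pde10a in dosed striatum was 714 ± 80.2, 663.7 ± 84.2 and 704.9 ± 102 CPM with rising dose, and none of these differences from vehicle was called (adjusted p of at least 0.535).

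Compared to WT striatum, Q175 vehicle striatum had lower levels of every one of the 22 MSN identity genes (22 adjusted over the list alone), with a median log2 change of -1.06. The ryanodine receptor Ryr1 fell by 3.18 ± 0.0944, the sodium channel subunit Scn4b by 2.20 ± 0.0933, the cannabinoid receptor Cnr1 by 1.72 ± 0.0751 and the phosphoprotein gene Arpp21 by 1.30 ± 0.0646 (adjusted p = 5.02e-29, 1.38e-23, 3.4e-23 and 3.11e-21). Of the indirect-pathway genes 5 of 6 fell (5 adjusted over the list alone, median -1.20): the enkephalin precursor Penk (-1.68 ± 0.0739), the adenosine receptor Adora2a (-1.45 ± 0.099), the orphan receptor Gpr6 (-1.32 ± 0.0927) and Drd2 (-1.07 ± 0.0929). Of 9 direct-pathway genes 5 fell and 2 rose (6 and 2 adjusted over the list alone). Only 1 rose without Q175 vehicle F5 or M2 or WT F2. The lower ones included the muscarinic receptor Chrm4 (-1.45 ± 0.0676), the dopamine receptor Drd1 (-1.20 ± 0.075) and the dynorphin precursor Pdyn (-0.83 ± 0.105). With an estimated correlation the adjusted p was 0.0578 for MSN identity, 0.0867 for the indirect and 0.347 for the direct list.

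**Figure D1:**
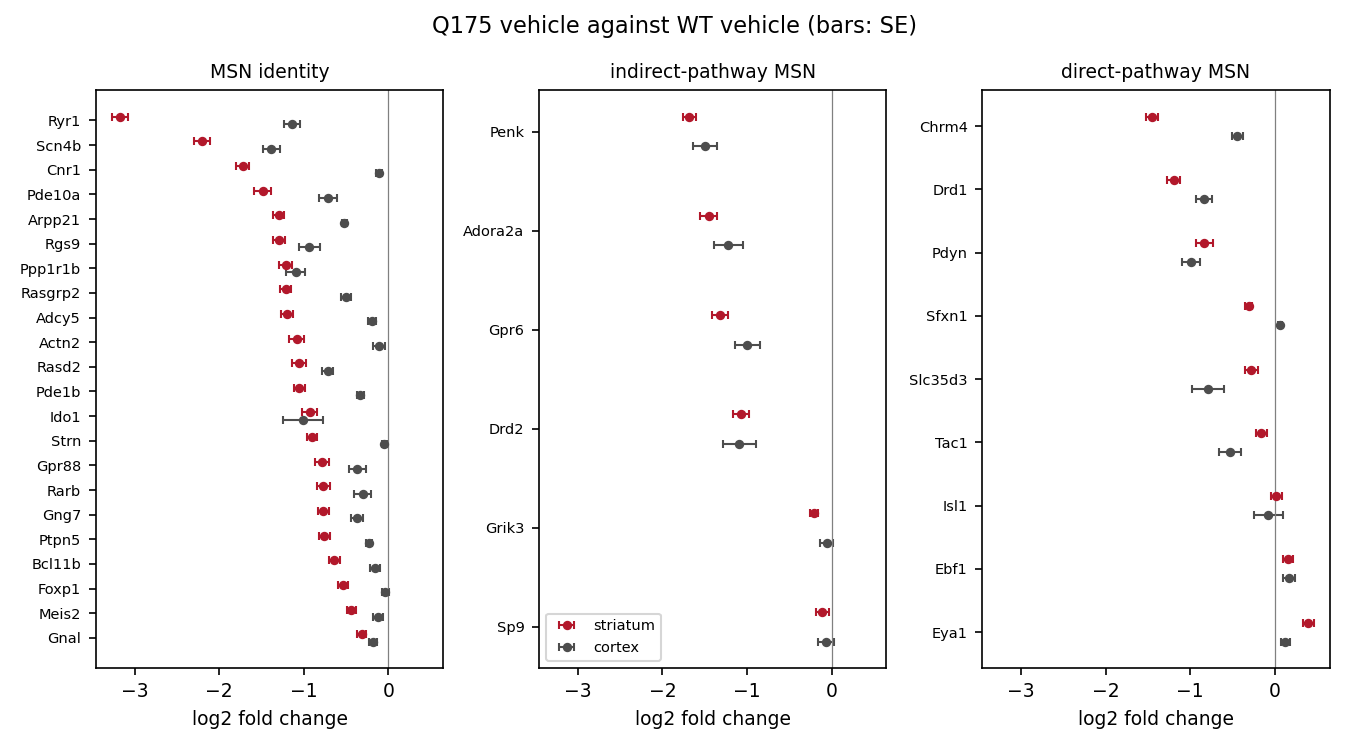
Log2 fold change of each measured gene of the MSN identity, indirect-pathway and direct-pathway lists in Q175 vehicle against WT vehicle mice, in striatum (red) and cortex (grey); points are the fitted values and bars their SE, with 7 Q175 and 9 WT mice. All 22 MSN identity genes lie below 0 in the striatum, and 18 of them were called lower in the cortex.

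Genes induced by neuronal activity and cyclic AMP were also lower in Q175 vehicle striatum. Of 24 activity and CREB-target genes 17 fell and none rose (17 adjusted over the list alone, median -0.70), including the scaffold gene Homer1 (-1.04 ± 0.115), the clock gene Per1 (-0.98 ± 0.15), the immediate early gene Egr1 (-1.12 ± 0.176) and the activin subunit Inhba (-1.10 ± 0.177). Adjusted p was 0.347 with an estimated correlation. Without WT M1, 1 gene rose. Of the cyclic nucleotide machinery 13 of 30 genes fell and 5 rose (13 and 5 adjusted over the list alone), and the lower ones included the adenylate cyclase Adcy5 (-1.19 ± 0.0695) and the phosphodiesterases Pde1b (-1.05 ± 0.0636) and Pde7b (-0.56 ± 0.0722). The median of this list, -0.10, turned to 0.03 on FPKM values, where 9 fell and 7 rose. Of 24 neurotransmitter receptors 17 fell and 4 rose (17 and 4 adjusted over the list alone, median -0.39, adjusted p = 0.19 with an estimated correlation). The GABA receptor subunit Gabrd fell by 1.13 ± 0.0567, whereas the serotonin receptor Htr2c rose by 0.96 ± 0.0608.

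Developmental transcription factors rose from near 0 in Q175 vehicle striatum. Of the 9 measured members 7 rose and none fell (7 adjusted over the list alone, median 5.13, adjusted p = 8.19e-06 with an estimated correlation). Onecut1 rose by 6.36 ± 0.229, from 0.0641 ± 0.0765 to 6.05 ± 0.686 CPM, Wt1 by 5.81 ± 0.175, Pou4f1 by 5.13 ± 0.324 and Pax2 by 5.22 ± 0.494 (adjusted p = 4.98e-26, 5.02e-29, 1.33e-17 and 3.74e-12). The homeobox gene Hoxc5 had 0 counts in all 9 WT libraries and 2.32 ± 0.426 CPM in Q175 vehicle mice, at least 259-fold higher against a floor of 3 counts over the WT group. Its overlapping neighbour Hoxc4 had 3 counts in WT striatum, a ratio of 398 with a 95% counting interval of 136 to 1930. The other genes with the largest rise were Lmx1b (6.41 ± 0.301), Shox2 (4.46 ± 0.253) and the noncoding RNA Crnde (2.82 ± 0.115). Beta protocadherins, cell adhesion genes in 1 cluster, rose in 16 of 21 cases and fell in 1 (16 and 1 adjusted over the list alone, median 0.52, adjusted p = 0.108 with an estimated correlation). Examples are Pcdhb3 (1.11 ± 0.0775) and Pcdhb22 (0.82 ± 0.0534), whose shared sequence makes single values uncertain.

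The genes with the largest fall in Q175 vehicle striatum were the glutathione peroxidase Gpx6 (-5.05 ± 0.238, from 7.96 ± 2.72 to 0.243 ± 0.0978 CPM), the protease Tmprss6 (-3.60 ± 0.326), Sec14l3 (-3.44 ± 0.144), the transporter Slc4a11 (-3.41 ± 0.175), Abhd11os (-3.22 ± 0.192), Vwa7 (-3.19 ± 0.23), Ryr1 and the activin-binding protein Fst (-2.81 ± 0.198), with adjusted p of 9.94e-13 or less. Abhd11os lies opposite another gene, and reads of the pair cannot be told apart without strand. In total 7817 of 17315 genes were called, 3794 higher and 4023 lower, and 538 of them changed by more than 2-fold. On log2(FPKM + 0.1) values 7223 of 9595 called genes were higher and 2372 lower, and the median of all genes stood at 0.11, so directions of small changes depend on the scaling.

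Among glia, 10 of 13 astrocyte genes fell and 2 rose in Q175 vehicle striatum (10 and 2 adjusted over the list alone, adjusted p = 0.347 with an estimated correlation). The bicarbonate transporter Slc4a4 fell by 0.52 ± 0.0494, the glutamate transporter Slc1a2 by 0.52 ± 0.0525 and Aldoc by 0.43 ± 0.0585, and the calcium-binding protein S100b rose by 0.45 ± 0.0676. Of 14 microglia genes 4 rose (1 adjusted over the list alone), including Ctss (0.39 ± 0.0735), 1 without Q175 vehicle F5 or M1 and 2 without vehicle M2 or WT F4, F5 or M1. Of 13 oligodendrocyte genes 5 fell (5 adjusted over the list alone), including the myelin genes Mobp (-0.63 ± 0.0946) and Mal (-0.61 ± 0.0865), with a list median of -0.07 that turned to 0.04 on FPKM values, where 4 fell and 5 rose. Without Q175 vehicle F1 this oligodendrocyte median was -0.04. Of 8 precursor genes 2 rose (2 adjusted over the list alone), among them Bmp4 (0.66 ± 0.136). In the endothelial and pericyte list 3 of 14 fell (3 adjusted over the list alone), including Slco1a4 (-0.29 ± 0.0574), and the median of -0.10 turned to 0.02 on FPKM values, where 1 fell. The direction tests of these last 4 lists gave adjusted p of at least 0.191.

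Interneuron markers were lower in Q175 vehicle striatum. All 5 cholinergic genes fell (5 adjusted over the list alone, median -0.44, adjusted p = 0.249 with an estimated correlation), including the acetylcholine-synthesizing enzyme Chat (-0.63 ± 0.0667) and the choline transporter Slc5a7 (-0.58 ± 0.0684). Of 8 GABA interneuron genes 5 fell (5 adjusted over the list alone), including Npy (-0.39 ± 0.0678). The interferon response list had 6 of 15 genes higher (5 adjusted over the list alone, median 0.31, adjusted p = 0.845 with an estimated correlation), among them Irf7 (0.78 ± 0.176).

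The remaining lists had no called direction in the striatum. Of 13 p53 targets 1 rose and 3 fell (1 and 3 adjusted over the list alone): the receptor Eda2r rose by 0.83 ± 0.161, and the kinase Plk2 and the cell cycle inhibitor Cdkn1a changed by -0.63 ± 0.0776 and -0.81 ± 0.237. The median of this list, -0.03, turned to 0.09 on log2(FPKM + 0.1) values, where 3 rose and 3 fell, and was -0.02 without Q175 vehicle F3 or WT F1. In this list 2 rose without WT F1, F2 or F5. Of 23 cholesterol biosynthesis genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), with Msmo1 at -0.47 ± 0.0663 and Insig1 at -0.51 ± 0.109. Its median of -0.08 turned to 0.04 on log2(FPKM + 0.1) values, where 7 rose and 3 fell. The 1 rise was not called without Q175 vehicle F1, F2 or F4 or WT F1, M2, M3 or M4, and 2 rose without WT F2. Of 15 chaperones 5 rose and 2 fell (5 and 2 adjusted over the list alone), with Hspa8 at 0.34 ± 0.0415 and Hsp90aa1 at 0.30 ± 0.0414, and the median (0.02) and mean (-0.0048) of the list differed in sign; 1 fell without Q175 vehicle M2. Oxidative phosphorylation had 5 lower and 2 higher of 24 (4 and 1 adjusted over the list alone), cytosolic ribosomal proteins 1 lower of 19 (Rps19, -0.23 ± 0.0433; 1 adjusted over the list alone), and the medians of both, -0.05 and -0.04, were above 0 with GC and length offsets and on FPKM values. With offsets 4 respiratory chain genes rose and 4 fell, and 2 ribosomal ones rose and 1 fell, while on FPKM values 10 rose and 0 fell (limma), and 8 rose and 1 fell.

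These respiratory chain and ribosomal counts in the striatum also depend on single libraries. For the respiratory chain they were 4 lower and 1 higher without Q175 vehicle F1 or WT F3, 3 and 1 without vehicle F2, 6 and 1 without vehicle M1, WT F4 or WT M3, and 7 and 1 without WT F2. They were 4 and 4 without vehicle M2, 3 and 3 without WT F1, and 3 and 4 without WT F5. Of the ribosomal genes 2 fell without vehicle M2, 3 without WT F4 and 4 without WT M1, and 1 rose without vehicle F3, vehicle F4 or WT F5. The oxidative phosphorylation median of -0.05 was -0.02 without WT F1 and -0.03 without vehicle F3. The cytosolic ribosomal protein median of -0.04 was -0.02 without WT F1 or F5 and -0.06 without WT M1.

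In Q175 vehicle striatum none of 12 choroid plexus and 7 ependymal genes was called (edgeR; 0 adjusted over the list alone), nor any of 5 blood genes (0 adjusted over the list alone), but 1 choroid plexus gene was higher without WT M4. On log2(FPKM + 1) values the ependymal median of -0.04 turned to 0.06 and the blood median of 0.46 to -0.13, and without Q175 vehicle F4 the blood median was -0.69 with 5 of 5 genes lower. The thalamus and hypothalamus list had 1 of 7 lower (Synpo2, -0.72 ± 0.0962; 1 adjusted over the list alone), and 2 without Q175 vehicle M1, with a median of 0.04 and a mean of -0.04. Single libraries moved this thalamus and hypothalamus median from -0.22 (without Q175 vehicle M1) to 0.14 (without vehicle M2), and the ependymal one from -0.19 (without WT F1) to 0.10 (without vehicle M1). Of 10 cortical excitatory neuron genes 1 was higher (0 adjusted over the list alone; edgeR). Leaving out 1 library gave 1 lower gene as well (Q175 vehicle F4, M1 or M2, WT F4 or M1), 2 lower ones (WT M2, M3 or M4) or 2 higher ones (WT F2). The direction test went against the median for the ependymal, blood, and thalamus and hypothalamus lists.

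Compared to WT cortex, Q175 vehicle cortex also had lower medium spiny neuron, activity and interneuron genes, higher interferon genes, and developmental transcription factors that rose. Which cells of the cortex samples carried the medium spiny neuron transcripts was not measured. In total 5356 of 17603 genes were called, 2463 higher and 2893 lower, 202 of them over 2-fold. Of the MSN identity list 18 of 22 fell (18 adjusted over the list alone, median -0.35, adjusted p = 0.0634 with an estimated correlation), with Scn4b at -1.38 ± 0.104, Ryr1 at -1.14 ± 0.0957, the GTPase Rasd2 at -0.72 ± 0.0613 and Arpp21 at -0.52 ± 0.0318. Penk (-1.50 ± 0.142) and Adora2a (-1.22 ± 0.174) were among 4 of 6 indirect-pathway genes that fell, and Pdyn (-0.99 ± 0.108) and Drd1 (-0.83 ± 0.0942) among 5 of 9 direct-pathway genes, of which 1 rose. Adjusted over the list alone, 4 indirect genes fell, and 5 direct genes fell and 3 rose. Without Q175 vehicle F1 or F5 or WT F5, 2 direct genes were called higher. Adjusted p with an estimated correlation was 0.156 and 0.321 for these lists.

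Of the activity and CREB-target genes 20 of 24 fell in Q175 vehicle cortex (21 adjusted over the list alone, median -0.62, adjusted p = 0.156 with an estimated correlation). Nptx2 (-0.96 ± 0.0979), Homer1 (-0.69 ± 0.095), the neurotrophin Bdnf (-0.52 ± 0.0791) and Egr2 (-1.61 ± 0.24) are examples. Cyclic nucleotide genes fell in 16 of 30 cases and rose in 2 (16 and 3 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation), with the guanylate cyclase subunit Gucy1a1 at -0.43 ± 0.0463 and Pde1b at -0.33 ± 0.0399. Of 24 receptors 13 fell (13 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation), including Gabrd (-0.85 ± 0.0379) and the opioid receptor Oprk1 (-0.86 ± 0.11). GABA interneuron genes fell in 7 of 8 cases (7 adjusted over the list alone, median -0.30, adjusted p = 0.00372 with an estimated correlation), with Vip at -0.70 ± 0.053, Npy at -0.47 ± 0.0436 and Pvalb at -0.38 ± 0.0758. Of 10 excitatory neuron genes 6 fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.394 with an estimated correlation), with Slc30a3 at -0.48 ± 0.0417 and the glutamate transporter Slc17a7 at -0.18 ± 0.0287. Without Q175 vehicle F4 or M2 or WT M3, 4 of this list fell and 1 rose. Of 5 cholinergic genes 3 fell (4 adjusted over the list alone; adjusted p = 0.463 with an estimated correlation), and 1 without Q175 vehicle F2 or F3 or WT F5 or M4.

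The interferon response rose in Q175 vehicle cortex in 14 of 15 genes (14 adjusted over the list alone, median 0.41, adjusted p = 0.171 with an estimated correlation), with Irf7 at 1.03 ± 0.145, Oas1a at 0.87 ± 0.155 and Oasl2 at 0.72 ± 0.121. Of 13 astrocyte genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.0349 with an estimated correlation), including Aldoc (-0.50 ± 0.0614) and Slc1a2 (-0.44 ± 0.0559). Of 14 microglia genes 4 rose (7 adjusted over the list alone; adjusted p = 0.463 with an estimated correlation), and 7 without Q175 vehicle F1. Of 23 cholesterol genes 11 fell (11 adjusted over the list alone, median -0.13, adjusted p = 0.394 with an estimated correlation), among them Fdft1 (-0.24 ± 0.0423). Developmental transcription factors rose in 6 of 11 cases (7 adjusted over the list alone, median 2.26, adjusted p = 0.000289 with an estimated correlation), and beta protocadherins in 7 of 21 (10 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation).

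The called genes with the largest rise in Q175 vehicle cortex were the transcription factors Shox2 (4.90 ± 0.374), Pou4f1 (3.97 ± 0.315), Pax2 (3.68 ± 0.193), Onecut1 (2.43 ± 0.16), Skor1 (2.29 ± 0.185) and Twist1 (2.27 ± 0.212), with Rgs13 (2.48 ± 0.168) and the tight junction gene Cldn14 (2.43 ± 0.16). Those with the largest fall were Slc4a11 (-2.04 ± 0.195), Ptprv (-1.996 ± 0.191), Cd4 (-1.86 ± 0.285), Tnfrsf25 (-1.76 ± 0.149), Fst (-1.73 ± 0.154), Alox12b (-1.70 ± 0.151), Egr2 and the kinase Plk5 (-1.60 ± 0.063), all with adjusted p of 1.21e-06 or less. Of the other lists, p53 targets had 1 of 13 higher and 6 lower (1 and 6 adjusted over the list alone), chaperones 5 of 15 higher and 4 lower (6 and 4), oxidative phosphorylation 3 of 24 higher (1), oligodendrocytes 2 of 13 higher and 5 lower (2 and 5), precursors 1 of 8 higher (1), endothelial cells 1 of 14 higher (0), ependymal cells 0 of 7 (0; edgeR), and ribosomal proteins 2 of 19 higher (0), the numbers in parentheses being adjusted over the list alone. Of 9 thalamus and hypothalamus genes 4 fell (4 adjusted over the list alone), including the neuropeptides Avp (-2.16 ± 0.557) and Oxt (-2.28 ± 0.611). Both had low counts. The mean log2 CPM was -2.11 for Oxt in the cortex, and -1.57 for Avp over both tissues of Q175 mice at 3.2 mg/kg and vehicle. Of 12 choroid plexus genes 1 rose (Sostdc1, 1.03 ± 0.335; 1 adjusted over the list alone), and of 5 blood genes none was called over all genes and 5 were higher adjusted over the list alone. The call of Sostdc1 ended without Q175 vehicle F2, and without vehicle F4 the blood median turned from 0.74 to -0.49 with 4 of 5 genes lower. Of the other lists, 1 respiratory chain gene was higher without WT F3, and 1 ribosomal one without Q175 vehicle F2, F4, F5, M1 or M2 or WT F1, F4 or M4. Endothelial genes were higher in 3 cases without vehicle F1, vehicle F3 or WT F2, in 2 without vehicle F5 or WT F3, and in none without vehicle F4, WT F4 or WT M2 (edgeR). Chaperones were lower in 1 case without vehicle M1 or WT M3 and in 2 without WT M2 or M4. Other single mice gave 1 to 5 higher blood genes (5 without vehicle F5, 3 without F3, 2 without M1, and 1 without F1, F2, M2, WT F5 or WT M1). Median and mean differed in sign for the chaperones (0.06 and -0.03) and the precursors (-0.02 and 0.03), and the thalamus and hypothalamus median of -0.01 stood beside a mean of -0.57. FPKM values turned the medians of the thalamus and hypothalamus, ependymal, precursor and blood lists across 0, and GC and length offsets those of the first 2. With these offsets 6379 genes were called, 3586 higher and 2793 lower, and on log2(FPKM + 0.1) values 6130, 4109 higher and 2021 lower.

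The genotype effects of the 2 tissues were compared within 16 vehicle mice. They differed for 3611 of 17455 genes, 1658 with a higher log2 change in the striatum and 1953 with a lower one. No difference in the change of Htt was called (0.03 ± 0.0491, adjusted p = 0.724), whereas Pde10a fell further in the striatum (-0.75 ± 0.1, adjusted p = 1.53e-05). Of the MSN identity genes 19 of 22 fell further in the striatum (19 adjusted over the list alone, median -0.51, adjusted p = 0.0533 with an estimated correlation), such as Cnr1 (-1.59 ± 0.0725), Adcy5 (-0.98 ± 0.0394) and Actn2 (-0.96 ± 0.0618). The largest differences were those of Lmx1b (5.36 ± 0.259), Onecut1 (4.01 ± 0.374), Wt1 (3.55 ± 0.318) and Nrn1 (2.54 ± 0.346) on the higher side, and of Gpx6 (-4.62 ± 0.708), Sec14l3 (-3.14 ± 0.177), Vwa7 (-2.68 ± 0.302) and Ryr1 (-2.002 ± 0.0889) on the lower side.

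For none of 6 indirect-pathway genes was a difference between the tissues in the genotype effect called (edgeR; 0 adjusted over the list alone). However, 1 was lower without Q175 vehicle F2, F3, F4 or M2 or WT F1, F4 or M4. By contrast 3 of 9 direct-pathway genes were higher and 3 lower (3 and 3 adjusted over the list alone; median 0.12, mean -0.04), with Chrm4 at -1.01 ± 0.0778 and Drd1 at -0.36 ± 0.0747. This direct-pathway median was 0.01 without Q175 vehicle F2, 0.05 without vehicle F3, 0.18 without vehicle F4 and 0.06 without WT M4. Of the activity and CREB-target genes 9 of 24 fell further in the striatum and 2 less (9 and 3 adjusted over the list alone, adjusted p = 0.982 with an estimated correlation), with Egr1 at -0.52 ± 0.0882 and Npas4 at -0.47 ± 0.091. Only 1 fell less without Q175 vehicle F1, F3, F4, F5 or M2 or WT M1, M2, M3 or M4. Beta protocadherins were higher in the striatum by this measure for 13 of 21 genes and lower for 1 (14 and 1 adjusted over the list alone, adjusted p = 0.0175 with an estimated correlation), the astrocyte filament Gfap by 0.63 ± 0.103, and 5 of 14 endothelial genes were lower (7 adjusted over the list alone, adjusted p = 0.763 with an estimated correlation), 3 without Q175 vehicle F4 or WT F3, F4, M2 or M3. In females alone 2354 genes differed.

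At 3.2 mg/kg, immediate early and CREB-target genes rose in Q175 striatum above Q175 vehicle. Of 24 members 19 rose and none fell (20 adjusted over the list alone, median 1.54, adjusted p = 5.04e-06 with an estimated correlation). The transcription factor Egr2 rose by 3.55 ± 0.418 (adjusted p = 5.27e-08), from 2.68 ± 1.16 CPM in vehicle mice to 32 ± 14.9 CPM, and stood at 15.2 ± 5.88 CPM in WT mice. Junb rose by 2.32 ± 0.225 (adjusted p = 7.43e-10), Fosl2 by 2.27 ± 0.28, Fos by 2.24 ± 0.296, Nr4a3 by 2.17 ± 0.272, Nr4a1 by 2.07 ± 0.283 and the phosphatase Dusp1 by 1.92 ± 0.175. Egr1 (1.72 ± 0.18) and the kinase Sik1 (1.58 ± 0.16) rose as well, and so did the receptor Gpr3 (2.02 ± 0.181), which is not in the list. Per mouse, the mean log2 CPM of the list lay 1.34 ± 0.341 above the Q175 vehicle mean in 9 mice at 3.2 mg/kg, and all 9 were above the highest vehicle mouse (exact permutation p = 8.74e-05, adjusted p = 0.000262 over 9 tests). WT mice lay 0.753 ± 0.256 above the same reference.

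**Figure D2:**
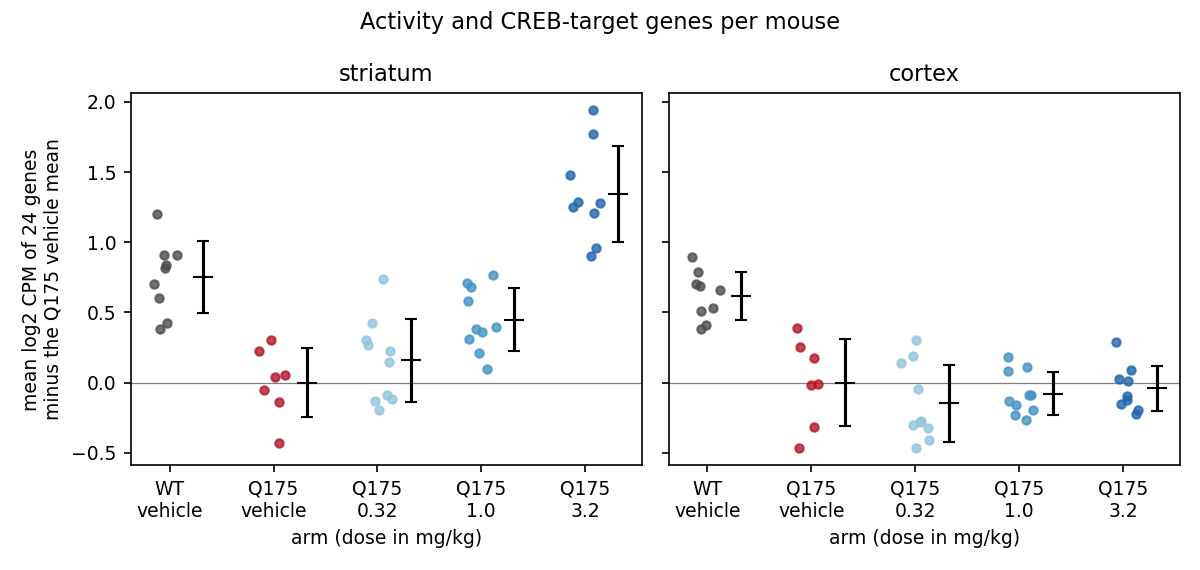
Mean log2 CPM of the 24 activity and CREB-target genes per mouse, minus the Q175 vehicle mean, in striatum and cortex for WT vehicle (9 mice), Q175 vehicle (7) and Q175 at 0.32 (10), 1.0 (10) and 3.2 mg/kg (9). Points are mice, and the bars beside them the mean and SD; striatal values at 3.2 mg/kg run from 0.904 to 1.94, above the highest Q175 vehicle mouse at 0.304.

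Genes of other lists were also called at 3.2 mg/kg in the striatum. The stress gene Gadd45b rose by 1.40 ± 0.138 and Plk2 by 0.51 ± 0.0774, 2 of 13 p53 targets (3 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation). Among 30 cyclic nucleotide genes the phosphodiesterases Pde4a (0.24 ± 0.0504, adjusted p = 0.00288) and Pde4d (0.28 ± 0.0647, adjusted p = 0.00827) rose (2 adjusted over the list alone; list median -0.02), and the chaperone Dnajb1 rose by 0.22 ± 0.0584. In the indirect pathway Gpr6 fell by 0.85 ± 0.093 (adjusted p = 1.06e-08), from 32.6 ± 3.46 to 18 ± 2.69 CPM, and Sp9 fell by 0.30 ± 0.0775. Penk rose by 0.26 ± 0.0708 (adjusted p = 0.0443). These are 2 lower and 1 higher of 6 (2 and 1 adjusted over the list alone, adjusted p = 0.712 with an estimated correlation). No member was higher without dosed F2, F3, F4, M2, M3 or M4 or vehicle F2, F3, F4, F5 or M1, and 1 was lower without dosed F1, F3, F5, M2 or M4 or vehicle F2, F5, M1 or M2. Other genes with the largest fall were Cited4 (-0.48 ± 0.0991), the serotonin receptor Htr4 (-0.48 ± 0.119), Otof (-0.45 ± 0.123) and the neuropeptide receptor Npy2r (-0.44 ± 0.0995), and Ryr1 fell by a further 0.34 ± 0.091. The call of Dnajb1 ended without dosed F2, F3, F4, M2 or M3 or vehicle F3, F4, F5, M1 or M2. That of Ryr1 ended without dosed F3, F5, M1, M2 or M4 or vehicle F2, F3, F4, F5 or M2.

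In total 257 of 17315 genes were called at 3.2 mg/kg in the striatum, 231 higher and 26 lower, 48 of them over 2-fold. Of the 231 higher genes 112 were among those lower in Q175 vehicle than in WT, against 53.7 for independent lists, but both comparisons share the 7 vehicle mice. The covariance of their log2 changes, -0.0119, stood beside -0.011 for simulated unchanged groups. With lane as a term 127 genes were called and 18 of 24 CREB-list members were higher (median 1.30).

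At 1.0 mg/kg, 4 of 24 activity and CREB-target genes rose in the striatum (12 adjusted over the list alone, median 0.49, adjusted p = 0.731 with an estimated correlation): Junb (1.02 ± 0.215, adjusted p = 0.0192), Arc (0.81 ± 0.205), Per1 (0.66 ± 0.147) and Vgf (0.42 ± 0.0933). Gpr3 (0.78 ± 0.178), Midn (0.64 ± 0.142), Gadd45b (0.54 ± 0.135) and the peptide transporter Tap1 (0.47 ± 0.12) were also higher, and Nrep (-0.30 ± 0.0709), Trpc4 (-0.26 ± 0.0622), Usp2 (-0.23 ± 0.0549) and the chaperonin Hspe1 (-0.14 ± 0.0344) lower. The list score per mouse rose by 0.449, with 8 of 10 mice above the highest vehicle mouse (exact permutation p = 0.00144, adjusted p = 0.00324). In total 186 genes were called, 138 higher and 48 lower. Lane and dose overlap here, since lane 1 held 5 of the 10 striatal libraries at 1.0 mg/kg and no striatal library of another arm. With lane as a term no gene was called (edgeR), the list median was 0.04 and Junb changed by 0.56.

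At 0.32 mg/kg, the only activity and CREB-target gene called in the striatum was Vgf (0.41 ± 0.0932, adjusted p = 0.0199; 1 adjusted over the list alone), a secreted neuropeptide precursor, and no difference of the list score from vehicle was called (0.157, exact permutation p = 0.268, adjusted p = 0.393). The genes with the largest rise included Rps13 (0.60 ± 0.152), C1qtnf4 (0.50 ± 0.0965), Pcsk1n (0.48 ± 0.1) and Ier5l (0.47 ± 0.0924), and the pseudogene Mid1-ps1 (1.69 ± 0.449), an uncertain value. The mitochondrial gene mt-Nd2 fell by 0.23 ± 0.0592. The share of reads on mitochondrial genes in the striatum was 9.85 ± 0.523% in Q175 vehicle, 8.79 ± 0.557%, 9.06 ± 0.547% and 9.28 ± 0.852% with rising dose, and 10.7 ± 0.649% in WT mice (not tested). In total 431 genes were called, 375 higher and 56 lower. The dependence of log2 CPM on GC content differed here too, with slopes per 10 percentage points of -0.0483 ± 0.0264 in Q175 vehicle, 0.055 ± 0.0522 at 0.32, 0.0248 ± 0.0819 at 1.0 and -0.0516 ± 0.0689 at 3.2 mg/kg. With GC and length offsets 14 genes were called at 0.32 mg/kg, 1 higher and 13 lower, and 2 at 1.0 mg/kg.

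Both lower striatal counts depend on single mice. At 0.32 mg/kg the count was 3 without Q175 vehicle F2, 51 without vehicle F1, 60 without vehicle F3, 123 without vehicle F5, 143 without vehicle F4, 165 without vehicle M1 and 805 without vehicle M2. It was 109 without dosed mouse F5, 122 without M5, 143 without F1, 166 without M3 and 270 without M4. The 1 CREB-list call at 0.32 mg/kg, Vgf, ended without vehicle F2 or F3. At 1.0 mg/kg the count was 22 without vehicle M1, 23 without vehicle F2, 40 without vehicle F3, 41 without vehicle F4, 63 without vehicle F5 and 346 without vehicle M2. It was 44 without dosed mouse F5, 55 without M1, 64 without M4, 64 without F3, 88 without M5, 96 without F2, 103 without M3 and 766 without M2. The 4 CREB-list calls at 1.0 mg/kg became 7 without vehicle F1, 2 without vehicle F3 or F4, and 1 without vehicle F2 or M1.

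The doses were also compared directly in the striatum, which does not involve the vehicle mice. At 3.2 against 0.32 mg/kg 20 of 24 activity and CREB-target genes were higher and 1 lower (21 and 1 adjusted over the list alone, median 1.44, adjusted p = 0.00465 with an estimated correlation), with Egr2 at 3.05 ± 0.344, Fos at 2.12 ± 0.255 and Dusp1 at 1.802 ± 0.152. Against 1.0 mg/kg 18 were higher and none lower (20 and 1 adjusted over the list alone, median 1.05, adjusted p = 0.00478 with an estimated correlation), with Egr2 at 2.14 ± 0.326, Dusp1 at 1.35 ± 0.15 and Crem at 0.57 ± 0.0711. Gpr6 was lower at 3.2 mg/kg than at 0.32 (-0.91 ± 0.0855) and at 1.0 mg/kg (-0.55 ± 0.0858), and Penk was higher (0.29 ± 0.0641 and 0.27 ± 0.0641). Pde4d (0.30 ± 0.0582) and Pde4b (0.19 ± 0.0393) were higher than at 0.32 mg/kg. Of 23 cholesterol genes 8 were higher than at 0.32 mg/kg (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.884 with an estimated correlation). Of 15 chaperones 7 were higher than at 1.0 mg/kg (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.407 with an estimated correlation), including Hspa8 (0.20 ± 0.0378). In total 1944 genes differed from 0.32 mg/kg, 868 higher and 1076 lower, and 911 from 1.0 mg/kg, 410 higher and 501 lower. With GC and length offsets the counts were 807 (528 higher, 279 lower) and 560 (431 higher, 129 lower).

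A linear trend over vehicle and the 3 doses was called for 304 striatal genes, 270 rising and 34 falling. Of the activity and CREB-target genes 20 of 24 rose (20 higher and 1 lower adjusted over the list alone, median 0.52 per dose step, adjusted p = 0.000434 with an estimated correlation): Egr2 by 1.27 ± 0.13, Junb by 0.77 ± 0.0708 and Per1 by 0.45 ± 0.0445 per step. Pde4a (0.07 ± 0.0139) rose, and Gpr6 (-0.30 ± 0.039) and Cited4 (-0.18 ± 0.0367) fell. Any of the 3 doses differed from vehicle for 1723 striatal genes. The trend called 117 genes with lane as a term and 620 with dose coded in mg/kg (422 higher, 198 lower), and the joint test called 1011 with lane and 686 with GC and length offsets.

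In the cortex of the same mice the score of the activity and CREB-target genes showed no called difference from vehicle, although 2 of its 24 members, Vgf and Egr4, fell at 0.32 mg/kg (2 adjusted over the list alone). Only 1 fell without dosed F1, F3, F4 or M5 or vehicle F1 or F2. At 1.0 mg/kg edgeR called none, but 3 fell without vehicle F5, 2 without vehicle M2 and 1 without dosed F1, M1 or M5. The score lay at -0.148 ± 0.273, -0.0789 ± 0.152 and -0.0424 ± 0.163 against Q175 vehicle with rising dose (exact permutation p = 0.306, 0.49 and 0.726). The rise in striatum minus that in cortex was 0.305 at 0.32 mg/kg (exact permutation p = 0.0247, adjusted p = 0.0445), 0.527 at 1.0 mg/kg (p = 5.14e-05, adjusted p = 0.000262) and 1.38 at 3.2 mg/kg (p = 8.74e-05, adjusted p = 0.000262, exact permutation tests). The difference at 0.32 mg/kg came from 0.157 in the striatum and -0.148 in the cortex, neither of them called. By gene, 20 of 24 had a higher change in the striatum than in the cortex at 3.2 mg/kg (21 adjusted over the list alone, median 1.58, adjusted p = 0.00248 with an estimated correlation). At 1.0 mg/kg 14 did so (16 adjusted over the list alone, adjusted p = 0.354 with an estimated correlation), including Junb (1.11 ± 0.131), Fos (0.93 ± 0.121) and Per1 (0.64 ± 0.0544). At 0.32 mg/kg 6 did so (6 adjusted over the list alone, adjusted p = 0.959 with an estimated correlation), including Egr4 (0.85 ± 0.208), Junb (0.81 ± 0.206) and Vgf (0.70 ± 0.0972). Of these 3 only Vgf was itself called higher in the striatum, and Egr4 and Vgf fell in the cortex. With GC and length offsets 7 were called at 1.0 mg/kg and 1 at 0.32 mg/kg. The effect of 3.2 mg/kg on Pde4a was also higher in the striatum (0.27 ± 0.0469) and that on Gpr6 (-0.76 ± 0.122) and Drd1 (-0.26 ± 0.0596) lower.

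In Q175 cortex, 0.32 and 1.0 mg/kg were accompanied by small changes in many genes, while at 3.2 mg/kg edgeR called none (1307 with an unadjusted p under 0.05; DESeq2 2, limma voom 5). Respiratory chain genes were higher in 6 of 24 cases at 0.32 mg/kg (12 adjusted over the list alone) and in 17 at 1.0 mg/kg (20 adjusted over the list alone), with Cox7c at 0.31 ± 0.0568 at the lower and Ndufa4 at 0.20 ± 0.0386 at the higher of these doses. Ribosomal protein genes were higher in 6 and 11 of 19 cases (6 and 13 adjusted over the list alone), with Rpl7 at 0.12 ± 0.0311 and 0.16 ± 0.0311. With an estimated correlation the adjusted p of both lists was 0.972 at 0.32 mg/kg and 0.832 at 1.0 mg/kg. At 0.32 mg/kg 3 respiratory chain genes were called without Q175 vehicle F2 or F4, and 3 ribosomal ones without vehicle F1, F2, F3 or F4, and at 1.0 mg/kg 7 ribosomal ones without dosed F1 or F4. The share of reads on mitochondrial genes was also higher in these arms, 8.77% and 8.69 ± 1.18% beside 7.57 ± 0.423% in vehicle and 7.56 ± 0.485% at 3.2 mg/kg (not tested). In the striatum it was lower than in vehicle at each dose. The interneuron peptides Vip (0.21 ± 0.0522 and 0.29 ± 0.0522) and Npy (0.14 ± 0.0429 and 0.18 ± 0.0429) were higher, and the glutamate receptor Grin1 (-0.22 ± 0.0423 and -0.20 ± 0.0424) and the precursor marker Cspg4 (-0.24 ± 0.0687 and -0.33 ± 0.0687) lower. The guanylate cyclase subunit Gucy1a2 (0.97 ± 0.199 and 0.84 ± 0.199) and the pseudogene Rps25-ps1 (1.14 ± 0.134 and 0.65 ± 0.134) had the largest rises. Vgf (-0.30 ± 0.075) and Egr4 (-0.44 ± 0.134) fell at 0.32 mg/kg.

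At 0.32 mg/kg 1789 cortical genes were called (912 higher, 877 lower) and at 1.0 mg/kg 3649 (1924 higher, 1725 lower), with a median absolute log2 change of 0.142 and 0.155. The dependence of log2 CPM on GC content differed between these arms, with a slope per 10 percentage points of GC of 0.0469 ± 0.0301 in Q175 vehicle, -0.0526 ± 0.048 at 0.32, -0.04 ± 0.0367 at 1.0 and -0.00279 ± 0.0391 at 3.2 mg/kg. With GC and length offsets 172 genes were called at 0.32 mg/kg (108 higher, 64 lower) and 880 at 1.0 mg/kg (651 higher, 229 lower), and with lane as a term 327 and 2540. The 1.0 mg/kg libraries F1 and F4, which had the lowest Htt of their arm (72.74 and 79.16 CPM), stood apart from the rest, and without them 2138 genes were called at that dose. They were the only cortex libraries of that dose in lane 3, which also held 2 cortex libraries at 0.32 mg/kg and 2 of WT mice. The 0.32 mg/kg count was 923 without Q175 vehicle F2 and 1027 without vehicle F4.

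At 3.2 mg/kg no cortical gene was called by edgeR, 1307 having an unadjusted p under 0.05. DESeq2 called 2 genes and limma voom 5. The smallest p-values belonged to Cacng8 (-0.23 ± 0.0447, adjusted p = 0.134), Map1s (-0.17 ± 0.0362, adjusted p = 0.185), Igsf8 (-0.14 ± 0.0323, adjusted p = 0.362) and Rprml (-0.23 ± 0.0555, adjusted p = 0.362). Leaving out dosed mouse F2 gave 1 call. No gene had a called trend with dose in the cortex (edgeR; 756 with an unadjusted p under 0.05, none by DESeq2 or limma voom), and Pcdh8 (-0.06 ± 0.0156), Slc9a9 (0.06 ± 0.0148) and Tbx3 (-0.13 ± 0.0326) were among those with the smallest p (adjusted p = 0.949). Any of the 3 doses differed from vehicle for 2708 cortical genes, 501 with GC and length offsets and 1237 with lane as a term.

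**Figure D3:**
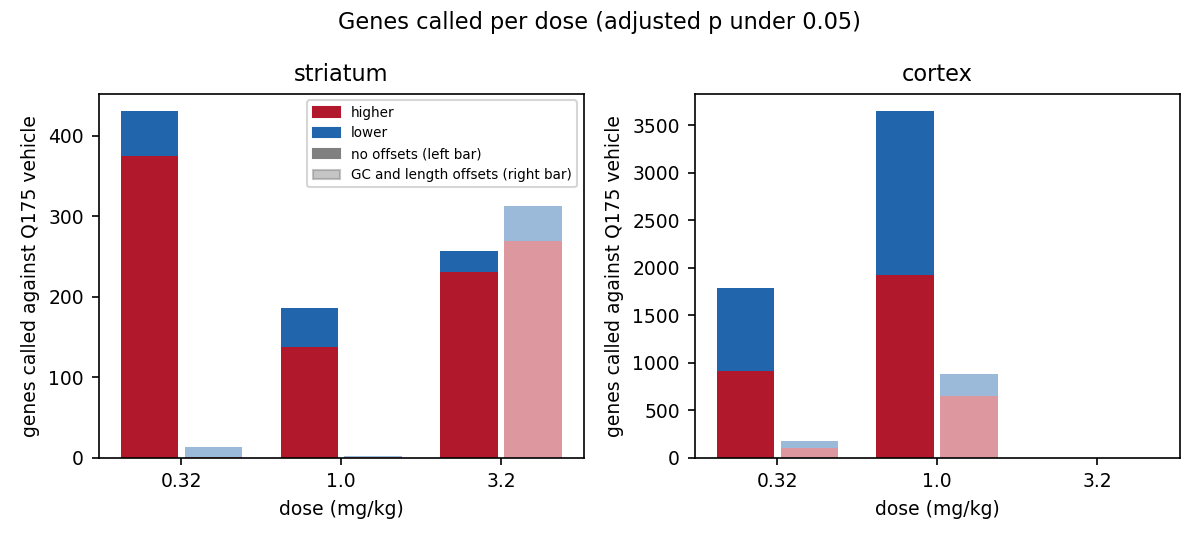
Number of genes called against Q175 vehicle per dose in striatum and cortex, higher (red) and lower (blue), without offsets (left bar, full colour) and with offsets for GC content and gene length (right bar, pale); bars start at 0. In the cortex the counts at 0.32, 1.0 and 3.2 mg/kg were 1789, 3649 and 0 without offsets and 172, 880 and 0 with them.

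Of 5 red cell genes 2, 2 and 3 were lower than in Q175 vehicle in the striatum with rising dose (5 each adjusted over the list alone), and 5 each in the cortex at 0.32 and 1.0 mg/kg. At 3.2 mg/kg in the cortex none was called (edgeR; 5 lower adjusted over the list alone, median -1.29). Alas2, an enzyme of heme synthesis, changed by -1.46 ± 0.391, -1.48 ± 0.392 and -1.54 ± 0.403 in the striatum with rising dose, and Hbb-bt by -1.34 ± 0.356, -1.45 ± 0.357 and -1.40 ± 0.365. In the cortex Alas2 (-1.46 ± 0.388 and -1.50 ± 0.388), Hbb-bt (-1.34 ± 0.376 and -1.37 ± 0.374) and Hba-a1 (-1.06 ± 0.327 and -1.11 ± 0.327) were lower at 0.32 and 1.0 mg/kg. Alas2 stood at 15.6 CPM in the striatum and 20.8 CPM in the cortex of Q175 vehicle F4, against at most 1.62 and 2.04 CPM in the other 6 vehicle mice. Without F4 the median of the 5 blood genes went from -1.01, -1.14 and -1.20 to 0.11, -0.01 and -0.11 in the striatum, from -1.09, -1.17 and -1.29 to 0.06, 0.01 and -0.06 in the cortex, and edgeR called no blood gene at any dose. The striatal calls also ended without dosed F1, F5, M3 or M5 or vehicle F1 or F2 at 0.32 mg/kg, without dosed F1, F2, F3, F4, F5, M1, M4 or M5 or vehicle F2 at 1.0 mg/kg, and without dosed F3, F4, F5 or M3 at 3.2 mg/kg. Only 1 was called without dosed M1 at 0.32 mg/kg and without dosed M3, vehicle F3 or vehicle M1 at 1.0 mg/kg, and 5 were called at 3.2 mg/kg without vehicle F1, F3, F5 or M1. In the cortex 2 were called at 0.32 mg/kg without dosed F1 or F2.

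Of 12 choroid plexus genes 2 were called lower in the cortex at 1.0 mg/kg (10 adjusted over the list alone, median -1.22, adjusted p = 0.832 with an estimated correlation), Clic6 at -0.87 ± 0.291 and the prolactin receptor Prlr at -1.24 ± 0.441. Mfrp, which was among the largest falls, changed by -1.50 ± 0.509. Neither GC and length offsets nor lane as a term left a call in this list, with medians of -1.25 and -1.09. The 2 calls depend on single libraries: 10 members were called without dosed F2 and 5 without vehicle F3, 1 without dosed F1, F5, M1, M3, M4 or M5 or vehicle F5 or M2, and none without dosed F4, vehicle F2 or vehicle M1 (edgeR).

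A genotype score asked whether dosing moved the whole profile along the axis from WT (0) to Q175 (1). In the striatum, Q175 vehicle mice scored 0.987 ± 0.0367, and the doses moved the score by 0.0108, 0.0277 and 0.0101 with rising dose (exact permutation tests, adjusted p = 0.536, 0.202 and 0.536; 9897 genes). As a percentage of the genotype difference, the 95% intervals ran from -2.54 to 4.76, from -0.609 to 6.18 and from -2.43 to 4.42, where a negative value is a move toward WT. In the cortex, Q175 vehicle mice scored 0.935 ± 0.0442, and 0.32 mg/kg moved the score away from WT by 0.0948 (exact permutation p = 0.00036, adjusted p = 0.00216; interval from 4.91 to 14.1%), with vehicle mice between 0.861 and 0.979 and dosed mice between 0.979 and 1.09. At 1.0 and 3.2 mg/kg the score moved by 0.106 and 0.0357 (exact permutation tests, adjusted p = 0.078 and 0.28). With signs as weights a move away from WT was called in the cortex at 1.0 mg/kg (0.19, adjusted p = 0.0054) and 3.2 mg/kg (0.0822, adjusted p = 0.021), and in the striatum at 1.0 mg/kg (0.0484, adjusted p = 0.0312; exact permutation tests). With GC and length offsets the cortical value at 0.32 mg/kg was 0.0466 (exact permutation test, adjusted p = 0.253), and over the 200 genes of smallest p it was -0.0224 (exact permutation test, adjusted p = 0.971). The axis is built from all Q175 mice, dosed ones included. On an axis from part of the vehicle mice this value was 0.0403 (2000 sampled permutations, adjusted p = 0.825), and in females it was 0.0676 (exact permutation test, adjusted p = 0.222).

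**Figure D4:**
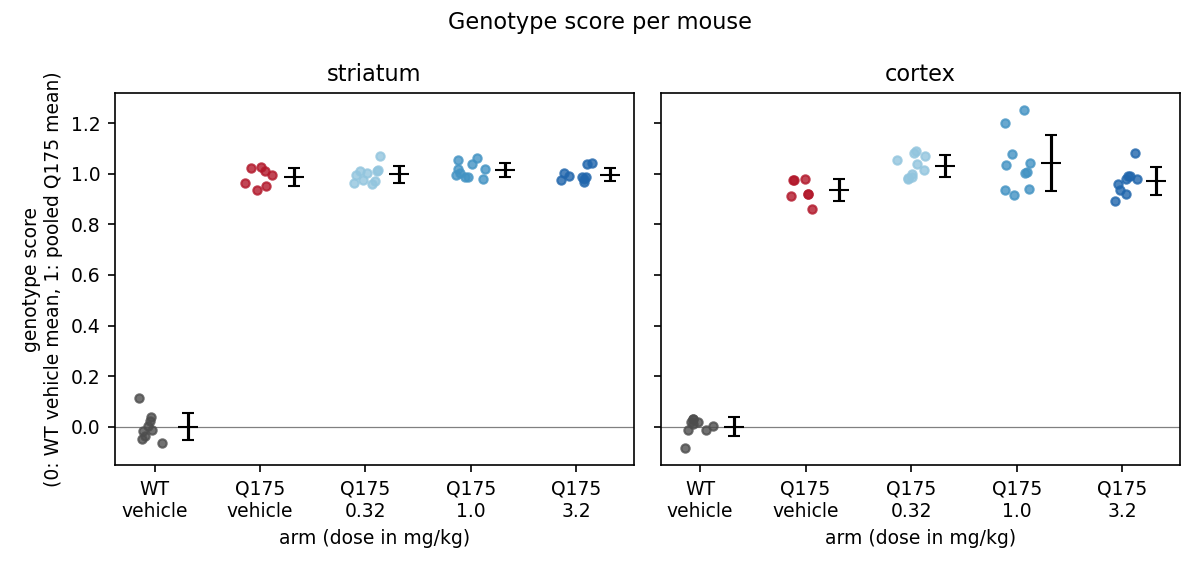
Genotype score per mouse in striatum (9897 genes) and cortex (8552 genes), with 0 at the WT vehicle mean and 1 at the mean of all Q175 mice. Points are mice, and the bars beside them the mean and SD; all striatal Q175 mice score between 0.934 and 1.07, and WT mice between -0.0628 and 0.115.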

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

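The GC and length offsets, the omission of the cortex libraries F1 and F4, the comparison of dose effects between tissues, and the CREB-list score with its test across both brain regions were chosen only after the data or the result had been seen.

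Red cell transcripts singled out 1 mouse. Alas2 stood at 15.6 CPM in the striatum of Q175 vehicle F4, with the other 6 mice of its group between 0.827 and 1.62 CPM, and at 20.8 CPM in its cortex, with the others between 0.878 and 2.04 CPM. The genotype score set apart striatal 0.32 mg/kg M3 (1.07, others 0.96 to 1.02) and cortical WT M3 (-0.0862, others -0.0141 to 0.0314). The total count of striatal 1.0 mg/kg M1 was 30.9 M, with the others between 37.5 M and 42.9 M. Of 70 groups examined in this way 5 had such a sample, and chance gives about 1 in 20. Effects differed between striatum and cortex for 3611 genes by genotype, 5265 genes at 0.32 mg/kg, 2262 at 1.0 mg/kg and 204 at 3.2 mg/kg, but with GC and length offsets for 809 at 0.32 and 252 at 1.0 mg/kg, and the CREB-list score rose by 1.38 more in the striatum at 3.2 mg/kg. GC and length bias also stays open for the striatal calls at 0.32 and 1.0 mg/kg. With offsets 14 and 2 genes were called, of which 3 and 1 were among the original 431 and 186 calls. The median size of the original calls fell from 0.216 ± 0.0558 to 0.0825 ± 0.0394 and from 0.214 ± 0.0519 to 0.127 ± 0.0437. In these median sizes, and in those of the cortical calls below, the value after ± is of the size of a single gene's SE. It is not the error of the median.

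Cortical genes such as Cox7c, Rpl7, Grin1 and Vip changed little but in large numbers at 0.32 and 1.0 mg/kg, while edgeR called no gene at 3.2 mg/kg (1307 with an unadjusted p under 0.05; 2 by DESeq2 and 5 by limma voom). Lane number does not account for most of the calls at 1.0 mg/kg: 2540 genes were called with it as a term, and 2421 of them were among the 3649. Lane was read from the L number in the labels. Some libraries share both the lane number and the LB number (meaning not given) in their labels, so a lane number may cover several runs. The term therefore cannot exclude a sequencing batch. A difference in GC and length bias between libraries may account for most of the calls at both doses: with offsets 172 and 880 genes were called, and the median size of the original calls fell from 0.142 ± 0.0392 to 0.0548 ± 0.0332 at 0.32 mg/kg and from 0.155 ± 0.0416 to 0.0786 ± 0.0367 at 1.0 mg/kg. The offsets would also take out a dose effect that follows GC content or length. The fall in calls therefore cannot tell such an effect from bias. Lane stays open at 0.32 mg/kg, where 327 genes were called with it, although the median size moved only to 0.131 ± 0.0436 while the value after ± rose. The share of F1 and F4 in the calls at 1.0 mg/kg cannot be told apart from that of dose, since without them 2138 genes were called and the median size was 0.116 ± 0.0377 beside 0.155 ± 0.0416, a partial fall, and a dose effect stays open as well. F1 and F4 were also the only cortex libraries of that dose in lane 3, with adjacent LB numbers, so their share overlaps with that of lane.

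Activity and CREB-target genes such as Egr2, Junb, Fos and Dusp1 were higher in the striatum at 3.2 mg/kg. GC and length bias is argued against by the list median of 1.55 with offsets, beside 1.54 without, and a single library by the lowest median of 1.42 when each was left out, reached without 3.2 mg/kg M2. Handling that reaches both regions of a mouse is argued against by the score, which rose more in the striatum than in the cortex of the same mice (1.38, exact permutation p = 8.74e-05, the smallest that the permutations can give). Handling that reaches the striatum alone, library preparation by arm, and the time between the last dose and collection were not tested. A candidate explanation that stays open is a response of striatal cells to PDE10A inhibition, where Pde10a itself was higher than in the cortex; this was not tested.

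Medium spiny neuron genes such as Penk, Drd1, Ryr1 and Scn4b were lower in Q175 vehicle striatum. A lower share of these neurons as the whole cause would raise the markers of all other cell types alike, but the astrocyte median (-0.228 ± 0.0385) and the microglia median (0.125 ± 0.0456) lay 8.16 standard errors apart and in opposite directions. GC and length bias is argued against by the list median of -0.994 with offsets, beside -1.06 without. A lower expression per neuron may underlie part of the change, and a smaller loss of neurons alongside it, or a change within astrocytes or microglia, stays open and was not tested.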

How the results depend on the processing

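GC and length offsets, leaving out the cortex libraries F1 and F4, contrasts of 2 doses, and dose effects by tissue with their alternatives were chosen after seeing the data. Of 330 counts of called genes under alternatives 251 stayed within 1.5 times the reported one, and the genotype counts of each tissue did so under all of them. For genes named here 6023 of 6614 values kept direction and call, 531 lost the call, 8 gained it, 50 changed sign where no change had been called (all of Htt or Pde10a), and 2 changed sign where one had. These 2 were Hba-a1, with -1.223 (without vehicle F5) to 0.0552 (without vehicle F4) for Hba-a1, cortex 0.32 mg/kg vs Q175 vehicle, and -1.269 to 0.0135 for Hba-a1, cortex 1.0 mg/kg vs Q175 vehicle. The 442 list tests include those without a call at the preset correlation. With an estimated correlation 77 lost their call, so the share of called lists that lost it is larger than 77 of 442. The cause was not tested, except where fewer libraries were used.

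The striatal counts at 0.32 and 1.0 mg/kg were the least stable: 140 and 56 without a filter, 837 and 683 with DESeq2, 1973 and 3021 with limma voom, 63 and 114 without the sex term, 95 and 387 in females only, 81 and 0 with lane, 60 and 1 with the replicate block, 14 and 2 with GC and length offsets, and 1358 and 394 with only the libraries of the 2 groups. Of these, DESeq2 gave 623 higher and 214 lower at 0.32 mg/kg, limma voom 1293 and 680, and FPKM values 170 higher and 28 lower at 1.0 mg/kg. At 3.2 mg/kg limma voom called 531 and lane left 127. For any dose in the striatum the counts were 4183 with limma voom, 1038 in females, 1011 with lane and 686 with offsets, and for the trend 148 in females, 117 with lane and 620 with dose in mg/kg.

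In the cortex at 0.32 mg/kg limma voom called 4047, females only 1148, lane 327, offsets 172, the libraries of the 2 groups 2822, omission of F1 and F4 2778, and this with offsets 351. At 1.0 mg/kg the counts were 880 with offsets, 1799 with the 2 groups, 2138 without F1 and F4, and 250 with offsets and without both. At 3.2 mg/kg they were 2 with DESeq2, 5 with limma voom and 1 without F1 and F4. For any dose they were 1237 with lane, 501 with offsets and 327 with offsets and without F1 and F4. Genotype by tissue gave 2354 in females. With offsets, 3.2 against 0.32 mg/kg gave 807, 3.2 against 1.0 mg/kg 560, and dose by tissue 809 at 0.32 and 252 at 1.0 mg/kg (75 higher, 177 lower). Without the mouse as a block, 3.2 mg/kg by tissue gave 133.

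Leaving out 1 library gave 3 to 805 calls in the striatum at 0.32 mg/kg, 22 to 766 at 1.0, 215 to 316 at 3.2 and 7342 to 7876 for the genotype. In the cortex it gave 923 to 2352, 2569 to 3940, 0 to 1 and 4896 to 5247, and by tissue for the genotype 3050 to 4033.

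Genotype scores (exact permutation tests, but 2000 sampled permutations for the axis from part of the vehicle mice; adjusted p in parentheses) changed sign on the 200 genes of smallest p at 0.32 and 3.2 mg/kg in the striatum (-0.000495 and -0.0072) and at each dose in the cortex (-0.0224, -0.00244 and -0.00749), in striatal females at 0.32 and 1.0 mg/kg (-0.0327 and -0.000805), and on an axis built from part of the vehicle mice at 0.32 and 3.2 mg/kg in the striatum (-0.00199 and -0.000573). With signs as weights a move away from WT was called in the striatum at 1.0 mg/kg (0.0484, 0.0312) and in the cortex at 1.0 (0.19, 0.0054) and 3.2 mg/kg (0.0822, 0.021). In the cortex at 0.32 mg/kg the call was lost in females (0.0676, 0.222), with offsets (0.0466, 0.253), with offsets and replicate block (0.0359, 0.381) and on that axis from part of the vehicle mice (0.0403, 0.825, sampled permutations). Without 1 library the scores were 0.0021 to 0.0188, 0.0197 to 0.0364 and 0.00263 to 0.0189 with rising dose in the striatum, and 0.0855 to 0.105, 0.0762 to 0.119 and 0.0226 to 0.0445 in the cortex. At 1.0 mg/kg in the cortex the score was called without F2 (0.118, 0.0405), M2 (0.119, 0.0345) or F5 (0.117, 0.0483) of that dose.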

Other observations

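The counts of single transcripts below were looked at only after their values had been seen, and the splits of the comparisons of 2 doses and of dose effects by tissue were chosen after seeing the data.

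Gm14303, a gene of a family with near-identical copies and so of uncertain count, was nearly absent from 1 arm. In the cortex it stood at 0.215 ± 0.285 CPM at 0.32 mg/kg, under 1 CPM in 10 of 10 libraries, beside 16 ± 5.17 CPM in Q175 vehicle and 20.1 ± 2.38 CPM in WT mice. The striatum of the same mice held 21.7 ± 5.23 CPM. In the striatum at 1.0 mg/kg F1, F2, F4, F5 and M4 stood between 7.6 and 11.2 CPM and the other mice between 18.7 and 23.9 CPM. Q175 vehicle striatum held 22 ± 3.95 CPM, and striatal 3.2 mg/kg M2 stood at 9.8 CPM. In the cortex at 1.0 mg/kg the 5 females stood between 0.0232 and 6.99 CPM (F1 0.423, F2 0.0232, F3 6.99, F4 3.96 and F5 0.492) and the 5 males between 13.1 and 23 CPM. At 3.2 mg/kg the level was 12.9 ± 4.52 CPM. Whether the cortex libraries at 0.32 mg/kg, or those of the females at 1.0 mg/kg, were prepared apart from the others is not stated in the sources used here. However, the LB numbers run in order of arm and sex in both tissues, where a label holds one. In the cortex those of the 0.32 mg/kg libraries and of the 1.0 mg/kg females follow on from each other. What the LB numbers stand for is not given, but their order is confounded with arm. A difference in preparation therefore stays open, untested, for the 1789 cortical calls and the score shift of 0.0948 at 0.32 mg/kg, and for the 3649 calls at 1.0 mg/kg. It stays open as well for the 186 striatal calls at 1.0 mg/kg, and for the 5265 and 2262 differences between tissues at 0.32 and 1.0 mg/kg. As the LB order follows arm in both tissues, the same holds for the 431 and 257 striatal calls at 0.32 and 3.2 mg/kg. These include the CREB-list genes at 3.2 mg/kg. It also holds for the genotype calls of both tissues.

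Ttr, a choroid plexus transcript, ranged from 6.56 to 1110 CPM over the cortex libraries. Its group levels were 209 ± 148 CPM in Q175 vehicle, 212 ± 337 at 0.32, 50.8 ± 92.2 at 1.0 and 140 ± 150 CPM at 3.2 mg/kg, and 113 ± 178 CPM in WT mice. Of the 24 activity and CREB-target genes 17 were lower in Q175 vehicle striatum and 19 higher at 3.2 mg/kg, 15 of them both, where independent lists would share 13.5. The 7 Q175 vehicle mice are in both comparisons, which by itself favours such an overlap. Btg2, Fos, Fosb and Vgf were called higher at 3.2 mg/kg but not called lower in Q175 vehicle.

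Dose effects against the same 7 vehicle mice share their chance values. In the striatum the log2 changes at 0.32 and 1.0 mg/kg correlated with r = 0.664, beside 0.593 for simulated unchanged groups and 0.188 with the vehicle mice split (covariance 0.0167 beside 0.0112). For 1.0 and 3.2 mg/kg the values were 0.514, 0.58 and 0.104 (0.014 beside 0.0109), and for 0.32 and 3.2 mg/kg 0.363, 0.577 and -0.00573 (0.00981 beside 0.0109). In the cortex 0.32 and 1.0 mg/kg gave 0.677, 0.588 and 0.321 (0.0211 beside 0.00957), 1.0 and 3.2 mg/kg 0.575, 0.569 and 0.173 (0.0142 beside 0.00958), and 0.32 and 3.2 mg/kg 0.563, 0.577 and 0.14 (0.0128 beside 0.00972). The covariances with 3.2 mg/kg thus lay above the simulated ones in the cortex, although no gene was called by edgeR at this dose (1307 with an unadjusted p under 0.05).

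Other splits of the same mice into groups of the same sizes were run for each count, 100 per comparison or 60 for the comparisons by tissue, and for WT striatum against cortex the tissue labels were exchanged within mice. In 17 of 19 comparisons only 1 split, the real one, gave as many calls, a share under 0.05. By that bar chance is argued against where the other splits stayed far below the real count, but it is not excluded. The splits run are only part of the possible ones, and the share was not adjusted over the 19 comparisons. For some counts the highest other split came close to the real one. Each real count is given with the highest of the other splits. In the striatum they were 7817 and 2618 for the genotype, 431 and 1 at 0.32 mg/kg, 186 and 135 at 1.0, 257 and 246 at 3.2, 1723 and 8 for any dose, 304 and 109 for the trend, 1944 and 9 for 3.2 against 0.32 mg/kg, and 911 and 493 for 3.2 against 1.0 mg/kg. In the cortex they were 5356 and 2932 for the genotype, 1789 and 69 at 0.32 mg/kg, 3649 and 2779 at 1.0, and 2708 and 8 for any dose. Between tissues they were 3611 and 470 for the genotype, 5265 and 1861 at 0.32 mg/kg, 2262 and 11 at 1.0, 204 and 0 at 3.2, and 12099 and 9456 for WT striatum against cortex. For 3.2 mg/kg and the trend in the cortex, where edgeR called no gene (1307 and 756 with an unadjusted p under 0.05; DESeq2 2 and 0, limma voom 5 and 0), all 100 splits gave as many, with highest counts of 2 and 48.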
